A study of Macrostomum lignano with 16 samples.

How the data were processed

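RNA was extracted with TRIzol from pools of whole worms in 4 social groups and made into libraries by an Illumina mRNA protocol, per the labels' protocols. They were read as single-end reads of 100 bp on an Illumina HiSeq, per the labels. Reads were aligned with Bowtie 0.12.7 and transcripts quantified with RSEM 1.1.19, per the submitters' processing notes. The reference was the transcriptome assembly MLRNA110815, per the file headers. The values are estimated counts per transcript as deposited by the authors, other than whole numbers in 23.8% of cells and written with 1 decimal and a decimal comma. RSEM divides reads that match several transcripts by estimation, so the values of similar transcripts depend on each other. The column totals differ, and no scaling for depth had been applied to them. Each column was assigned to its library by the header given in that library's label.

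The table holds 76437 transcripts, of which 2231 had 0 reads in all 16 libraries. Identifiers with a dot suffix (19394) mark transcripts that share a number, and the table holds 65252 distinct numbers. Estimated counts were rounded to whole numbers. Transcripts were kept when at least 4 libraries reached 1.26 CPM, equal to 10 reads in the library of median size, and the sum over libraries was at least 15, which is the rule of filterByExpr written out. This left 40265 transcripts that held 98.8% to 99.2% of the reads of each library. TMM scaling factors were computed with a trim of 30% for ratios and 5% for abundance. CPM values in the text use the library sizes after TMM scaling.

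The quasi-likelihood test of edgeR, named as the main test in the design fixed before the data were examined, was not used. DESeq2, named there as another test, was not used either. The decimal commas of the table kept its values from being accepted as counts in a check of units. The main test was limma-voom (limma 3.58.1 in R 4.3.3, pseudocount 0.5 in log2 CPM), 1 of the alternatives planned before the data were examined. A linear model with the 4 groups was fitted to all 16 libraries, so that the groups share 1 estimate of the spread, with 12 residual and 10.4 prior degrees of freedom. The 6 pairwise contrasts and the F-test over the group terms were taken from that fit with moderated statistics. Adjusted p-values are Benjamini-Hochberg values over all 40265 transcripts of 1 comparison, with a threshold of 0.05, and all tests were two-sided. Fold changes are on the log2 CPM scale with the pseudocount and understate changes of scarce transcripts. The scripts were tested on simulated counts with 50 transcripts changed at each of 4 fold sizes. For octet against isolated worms, 4% of 1.5-fold, 44% of 2-fold, 64% of 3-fold and 76% of 4-fold changes were recovered, and 4 unchanged transcripts of 40113 tested were called. The simulation called 98 transcripts in all, against 8640 in the data, and drew each transcript independently. Its rates test the scripts and need not hold for the real comparison.

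Depth was 7302416 to 10112451 estimated reads per library. The spread between pools, which includes counting error, gave a median 95% interval of 0.50 to 0.52 log2 units to either side of a fold change in the 6 comparisons. Transcripts were named by a rule fixed before the data were examined. For each comparison it takes at most 2 higher and 2 lower transcripts with the largest absolute log2 fold change, an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between the 2 groups. Each named transcript was then followed through all groups. The longer lists of gene names planned for camera and fry tests, covering testis, ovary, stem cell, gland, neural, stress, ribosomal, muscle and food alga genes, could not be matched to identifiers and gave no result. Checks of GC content and transcript length were not made, because no sequences were used here.

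The alternatives covered median-ratio and upper-quartile scaling, no filter and a stricter filter (more than 1 CPM in 4 libraries), unrounded values, the replicate number as a block, a threshold of 0.01, fits to the 8 libraries compared, and leaving out each library in turn. Added after the data were seen were limma-trend with a pseudocount of 2, a quality weight per library, leaving out paired replicate 4 with isolated replicate 3, leaving out RNA815_80.1 and summing transcripts that share a number. Correlations between comparisons with shared isolated libraries were set beside 20 simulations of unchanged groups and 6 splits of those libraries. No library was left out of the main results.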

Results

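Whole adults of Macrostomum lignano, a small free-living flatworm, were profiled by RNA sequencing. The species is a simultaneous hermaphrodite, in which each adult makes both sperm and eggs, and the study asked which transcripts respond to the social setting. All worms belonged to strain DV1 and were 66 to 69 days old. The 16 libraries fell into 4 social groups with 4 replicate pools of worms in each. Isolated worms had lived alone for 64 days, paired worms with 1 constant partner, and octet worms in groups of 8. Joined worms had lived alone until a partner was added for the last 24 h, a group meant to show the early response to mating. Because each library holds a pool, p-values measure the spread between pools and not between individual worms.

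The libraries held 7302416 to 10112451 estimated reads, with a mean of 8288091. The most abundant transcript, RNA815_80.1, took 9.17% to 21.5% of the reads of a library. Its share was 13.4% ± 3.86 in octet worms, 17.3% ± 3.04 in paired worms, 18.2% ± 3.43 in joined worms and 19.3% ± 3.13 in isolated worms (SD, n = 4 each). The number of transcripts with at least 1 read was 61723 ± 981 in octet worms and 65436 ± 349 in joined worms, with 63857 ± 1152 in paired worms and 63702.5 ± 1593 in isolated worms (SD, n = 4 each). The 24 pairs of libraries from the same group differed by more than sampling noise, with a chi-square per degree of freedom of 2.98 to 24.1, so none was treated as a library deposited more than once. That value does not show that the pools were independent. The deposited table does not pair its transcript identifiers with gene names, and transcripts are given by identifier only.

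The first principal component of log2 CPM (read counts scaled to a common library size) held 36.6% of the variance and ran from joined to octet worms. Octet libraries scored from -119 to -45.7, paired libraries from -59.5 to 25.3, isolated libraries from 7.66 to 57.7 and joined libraries from 38.3 to 74.5. Paired replicate 4, at -59.5, lay beyond octet replicate 3, at -45.7. On the second component, with 10.9% of the variance, isolated replicate 3 lay at -87.2 and the other isolated libraries between -8.74 and -2.40. Over all 4 groups, 9532 of the 40265 tested transcripts (23.7%) differed at an adjusted p under 0.05 (limma-voom, F-test over the group terms).

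**Figure D1:**
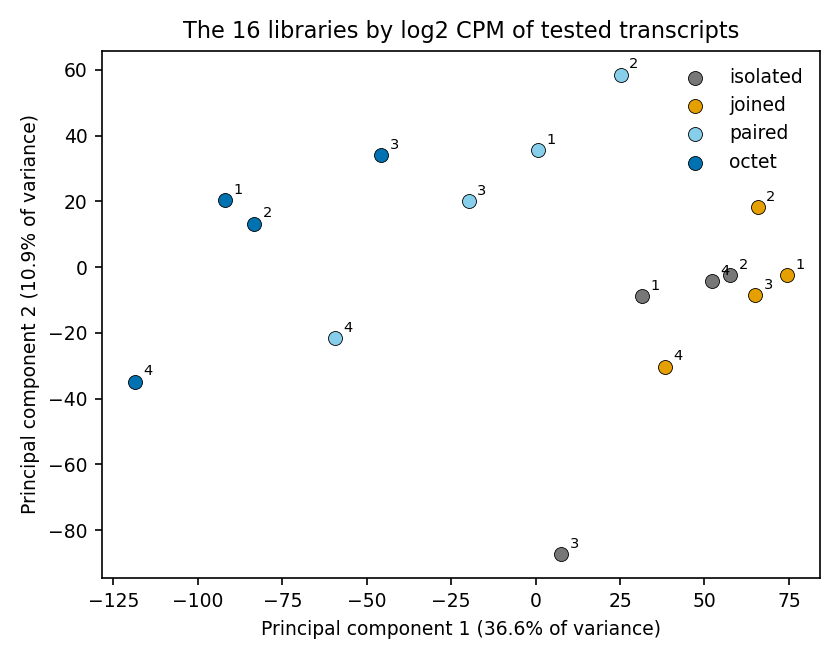
Scores of the 16 libraries on the first 2 principal components of log2 CPM (horizontal axis, 36.6% of the variance; vertical axis, 10.9%), 1 point per library, coloured by group and numbered by replicate. Octet libraries lie at the left (-119 to -45.7), joined libraries at the right (38.3 to 74.5), paired replicate 4 lies among the octet libraries on the horizontal axis, and isolated replicate 3 lies lowest, at -87.2 on the vertical axis.

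Octet and isolated worms represent the widest contrast in social group size. Under the naming rule the largest rise was in RNA815_29683.1, which went from 1.60 ± 0.75 CPM in isolated worms to 60.4 ± 20.1 CPM in octet worms (SD, n = 4 each), a log2 fold change of 5.25 with a standard error of 0.48. RNA815_38273 rose from 1.96 ± 0.71 to 67.8 ± 20.8 CPM, a log2 fold change of 5.09 with a standard error of 0.40. The largest fall was in RNA815_21158.1, from 644 ± 207 CPM in isolated worms to 32.8 ± 19.5 CPM in octet worms, a log2 fold change of -4.43 with a standard error of 0.34. RNA815_21158.2, whose identifier shares its number with that transcript, fell from 212 ± 60.3 to 27.2 ± 14.1 CPM, a log2 fold change of -3.08 with a standard error of 0.30. In each of these transcripts all 4 octet libraries lay beyond all 4 isolated libraries, which the naming rule requires. The limma adjusted p was 1.09e-07, 9.43e-09, 7.34e-09 and 3.11e-07 in that order. Reads of transcripts that share a number may have been divided between them by estimation, so the level of each is less certain than that of their family.

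In total 8640 transcripts (21.5%) differed between octet and isolated worms, 5157 of them higher and 3483 lower in octet worms (limma-voom, adjusted p under 0.05). The median absolute log2 fold change among them was 0.86. Changes above 2-fold were found in 1650 higher and 1410 lower transcripts, and changes above 4-fold in 184 higher and 119 lower transcripts. The groups did not overlap in 6733 of the called transcripts and in 22.2% of all tested ones, where chance gives 2.86%. Calls were more frequent among abundant transcripts, with 9.75% of the 13422 least abundant transcripts, 19.8% of the 13421 in the middle and 34.9% of the 13422 most abundant by mean log2 CPM. Among the most abundant 3170 rose and 1510 fell, and among the least abundant 580 rose and 728 fell. The split by direction depended on the scaling: with upper-quartile factors 4409 of 8926 calls (49.4%) were higher in octet worms, against 59.7% with TMM factors. Without octet replicate 1 the count was 5617.

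**Figure D2:**
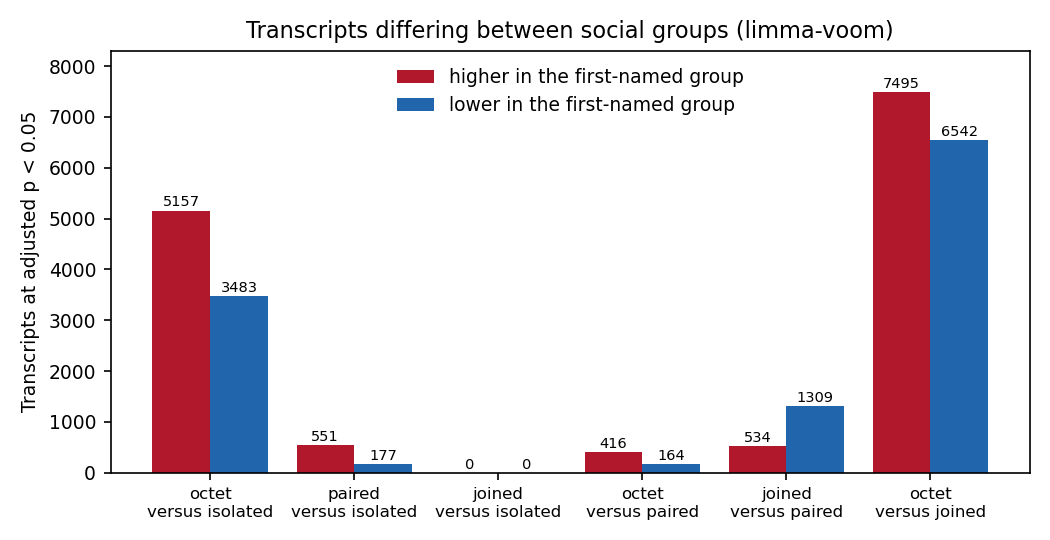
Number of transcripts at an adjusted p under 0.05 (vertical axis, limma-voom, 4 libraries per group) for each of the 6 comparisons (horizontal axis), higher in the first-named group in red and lower in blue. The bars run from 0 and 0 for joined against isolated worms to 7495 and 6542 for octet against joined worms.

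Paired and isolated worms differed by the presence of 1 constant partner. RNA815_324.1 rose from 8.66 ± 4.00 CPM in isolated worms to 155 ± 45.5 CPM in paired worms (SD, n = 4 each), a log2 fold change of 4.27 with a standard error of 0.41. RNA815_29683.1, which also led the rises in octet worms, stood at 30.5 ± 14.5 CPM in paired worms, a log2 fold change of 4.22 against isolated worms with a standard error of 0.49. RNA815_21158.1 fell to 25.9 ± 8.84 CPM, a log2 fold change of -4.63 with a standard error of 0.34, and RNA815_21158.2 fell to 27.0 ± 3.77 CPM, a log2 fold change of -2.93 with a standard error of 0.30. By the naming rule all 4 paired libraries lay beyond all 4 isolated libraries in each of these, with limma adjusted p values of 8.99e-07, 8.76e-06, 6.51e-08 and 1.87e-06.

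Paired worms differed from isolated worms in 728 transcripts (1.81%), with 551 higher and 177 lower (limma-voom). Among them, 106 rose and 18 fell by more than 4-fold. Among the 13422 most abundant transcripts 542 were called, against 51 among the 13422 least abundant. The count was 452 without paired replicate 1, 476 without isolated replicate 2 and 434 without isolated replicate 4. It was 415 in a fit to the 8 libraries of the 2 groups and 1656 with a quality weight per library, added after the data were seen.

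Joined worms, after 24 h with a partner, were compared with isolated worms to look for a short-term response. No transcript passed limma-voom at an adjusted p under 0.05, where the smallest adjusted p was 0.739. That smallest value was unstable: with 1 library left out it ran from 0.129 (without isolated replicate 4) to 0.9996 (without isolated replicate 3), still with 0 calls. At an unadjusted p under 0.05 there were 2371 transcripts (5.89%), and limma-trend also called 0, with 2235 at an unadjusted p under 0.05. Of the transcripts that marked constant company, RNA815_29683.1 was at 2.54 ± 1.07 CPM in joined worms, RNA815_38273 at 3.02 ± 1.53 CPM, RNA815_21158.1 at 541 ± 209 CPM and RNA815_21158.2 at 182 ± 64.2 CPM (SD, n = 4 each). Their log2 differences from isolated worms were 0.64, 0.52, -0.27 and -0.24, with standard errors of 0.57, 0.47, 0.32 and 0.28 in that order. None of them passed the test, but errors of this size do not show that the levels were equal. RNA815_324.1 was at 32.1 ± 13.2 CPM, a log2 difference of 1.92 from isolated worms with a standard error of 0.42, and did not pass the test over all transcripts. The median 95% interval of a fold change reached 0.50 to either side on the log2 scale. In simulated data for this comparison, 4% of transcripts changed 1.5-fold, 40% of those changed 2-fold and 78% of those changed 4-fold were recovered. There were 50 transcripts at each size among 40493 tested. Most changes of 1.5-fold and of 2-fold were therefore missed in the simulation, and some of 4-fold were missed too. A limma-voom fit to the 8 joined and isolated libraries alone called 3 transcripts, RNA815_34533.1, RNA815_34533.2 and RNA815_23273, all lower in joined worms and named after their values were seen. RNA815_34533.1 stood at 478 ± 52.2 CPM in isolated and 243 ± 31.9 CPM in joined worms (adjusted p = 0.0041 in that fit), and in constant company at 166 ± 69.8 CPM in paired and 194 ± 38.0 CPM in octet worms.

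**Figure D3:**
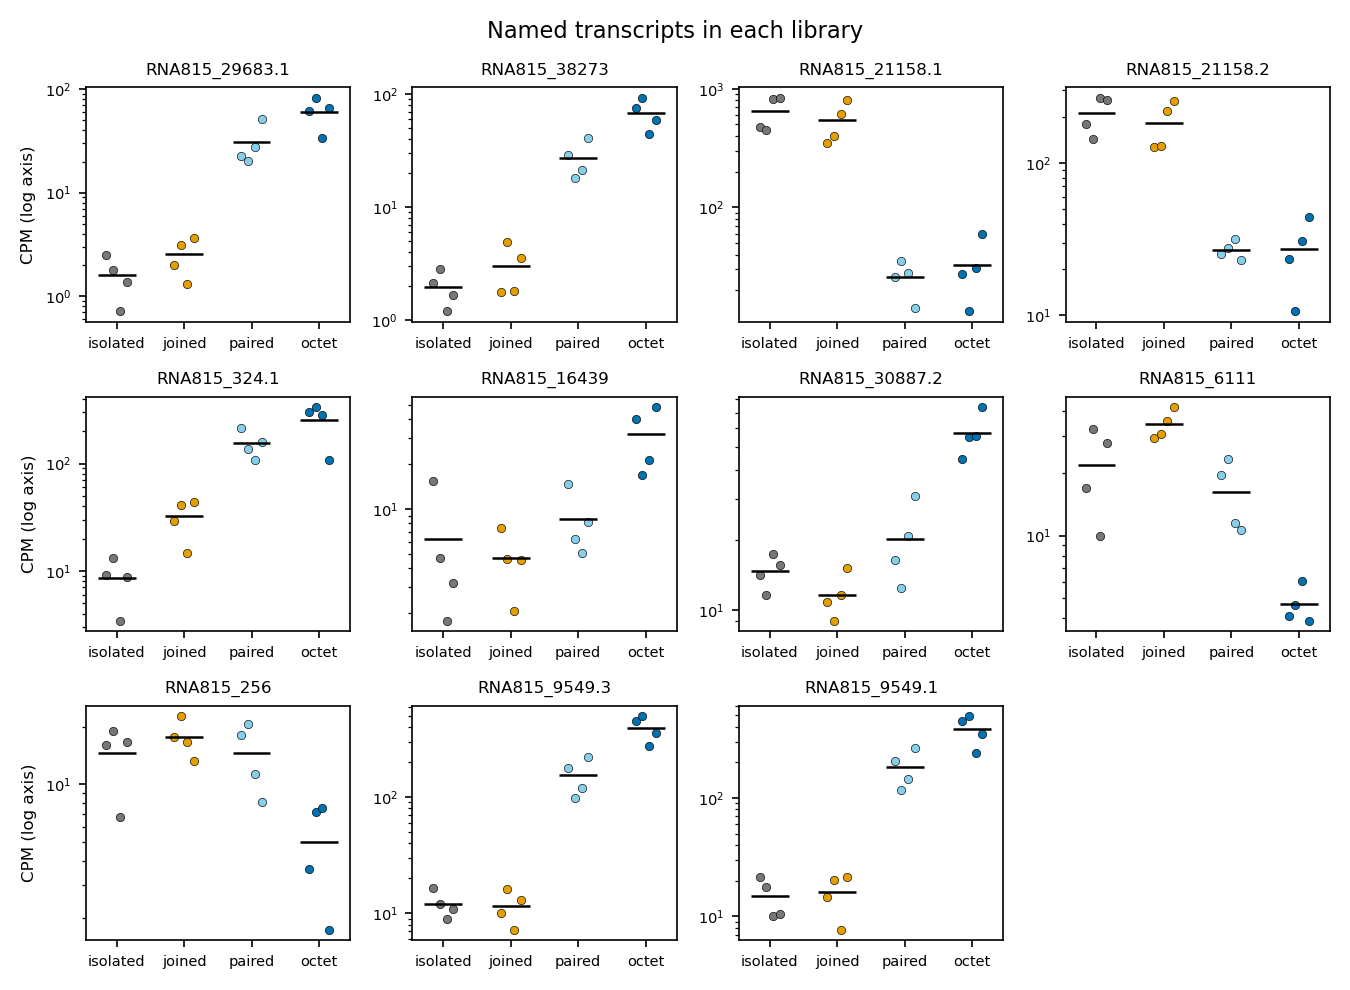
CPM of the 11 transcripts named by the fixed rule (vertical log axes) in the 4 groups (horizontal axis), with 1 point per library and a bar at the mean of 4 libraries. RNA815_29683.1 is at 1.60 CPM in isolated, 2.54 in joined, 30.5 in paired and 60.4 in octet worms, and RNA815_21158.1 is at 644, 541, 25.9 and 32.8 CPM in the same order.

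Octet and paired worms both had constant company and differed in group size. RNA815_16439 stood at 31.7 ± 15.0 CPM in octet worms and 8.57 ± 4.25 CPM in paired worms (SD, n = 4 each), a log2 fold change of 1.86 with a standard error of 0.42. RNA815_30887.2 rose from 20.1 ± 7.86 CPM in paired worms to 57.3 ± 12.2 CPM in octet worms, a log2 fold change of 1.58 with a standard error of 0.21. RNA815_6111 fell from 16.3 ± 6.23 to 4.68 ± 0.98 CPM, a log2 fold change of -1.74 with a standard error of 0.35, and RNA815_256 fell from 14.5 ± 5.83 to 5.02 ± 2.81 CPM, a log2 fold change of -1.66 with a standard error of 0.40. The limma adjusted p was 0.0331, 0.00192, 0.0223 and 0.0424 in that order, and by the naming rule the libraries of the 2 groups did not overlap in any of them. RNA815_16439, RNA815_6111 and RNA815_256 lost their call in 7, 5 and 10 of 27 alternatives, while RNA815_30887.2 kept its call in all 27. RNA815_21158.1, at 25.9 CPM in paired and 32.8 CPM in octet worms, showed a log2 difference of 0.21 with a standard error of 0.36 and did not pass the test between them.

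Octet worms differed from paired worms in 580 transcripts (1.44%), 416 higher and 164 lower (limma-voom), and 94 of the higher and 85 of the lower ones differed by more than 2-fold. Limma-trend with a pseudocount of 2, added after the data were seen, called 228 higher and 218 lower, so the excess of higher transcripts did not hold under every setting. The count depended on which libraries were present. It was 3988 without paired replicate 4, 2459 without octet replicate 3 and 1081 without isolated replicate 3. It was 34 without octet replicate 1, 274 without octet replicate 2, 53 without octet replicate 4, 40 without paired replicate 1, 51 without paired replicate 2 and 243 without paired replicate 3. Leaving out a library of neither group also lowered it, to 319 without joined replicate 1, 325 without isolated replicate 1, 366 without isolated replicate 2 and 353 without isolated replicate 4. A fit to the 8 libraries of the 2 groups alone gave 8, and a quality weight per library, added after the data were seen, gave 5421.

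Joined and paired worms had the same company on the last day and differed in what came before. RNA815_21158.1 was 20.6-fold higher in joined worms, a log2 fold change of 4.36 with a standard error of 0.34, and RNA815_21158.2 was 6.47-fold higher, a log2 fold change of 2.69 with a standard error of 0.30. RNA815_9549.3 was lower in joined worms, at 11.6 ± 3.87 CPM against 154 ± 56.0 CPM in paired worms (SD, n = 4 each), a log2 fold change of -3.73 with a standard error of 0.27. RNA815_29683.1 was lower by a log2 fold change of -3.59 with a standard error of 0.40. By the naming rule all 4 joined libraries lay beyond all 4 paired libraries in each of these, with limma adjusted p values of 7.16e-08, 5.59e-06, 6.88e-08 and 5.37e-06.

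Between joined and paired worms 1843 transcripts (4.58%) differed, with 534 higher and 1309 lower in joined worms (limma-voom). Among the lower ones 106 differed by more than 4-fold, against 12 of the higher ones. The count was 1038 without paired replicate 1, 1028 without paired replicate 3, 931 without joined replicate 1 and 1025 without joined replicate 3. With a quality weight per library, added after the data were seen, it was 3517.

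Octet and joined worms gave the longest list. RNA815_9549.3 stood at 395 ± 99.0 CPM in octet worms against 11.6 ± 3.87 CPM in joined worms (SD, n = 4 each), a log2 fold change of 5.12 with a standard error of 0.27. RNA815_9549.1 stood at 380 ± 111 against 16.0 ± 6.23 CPM, a log2 fold change of 4.64 with a standard error of 0.30. RNA815_9549.3 and RNA815_9549.1 belong to 6 transcripts that share a number, of which 5 were tested, and all 5 were called higher in octet worms. RNA815_21158.1 was lower in octet worms by a log2 fold change of -4.16 with a standard error of 0.34. RNA815_6111 was lower by a log2 fold change of -2.87 with a standard error of 0.34, from 34.4 ± 5.45 CPM in joined worms. The limma adjusted p was 6.99e-11, 7.86e-10, 1.43e-08 and 2.35e-06 in that order, and by the naming rule the groups did not overlap in any of the 4. Altogether 14037 transcripts (34.9%) differed, 7495 higher and 6542 lower in octet worms, with 195 and 333 of them beyond 4-fold. With upper-quartile factors the majority turned, to 6501 higher and 7754 lower.

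A set of 708 transcripts differed in the same direction from isolated worms in both octet and paired worms. Of these, 544 were higher and 164 lower in constant company, and no transcript was called in opposite directions in the 2 comparisons. RNA815_29683.1, RNA815_38273, RNA815_324.1, RNA815_9549.3 and RNA815_9549.1 belonged to the higher set, and RNA815_21158.1 and RNA815_21158.2 to the lower set. In the higher set the median log2 fold change against isolated worms was 1.29 in octet worms, 0.87 in paired worms and 0.07 in joined worms. In the lower set it was -1.28, -0.93 and -0.10. None of the 708 was called between joined and isolated worms (limma-voom), which had to be so, because that comparison called 0 transcripts in all. An unadjusted p under 0.05 was found there in 124 of the 708, against 2371 (5.89%) of the 40265 tested transcripts. The set was chosen with the same isolated libraries, so a larger share in it may be partly built in. Between joined and paired worms 546 of the 708 (77.1%) were called, 423 of them below and 123 above the paired level in joined worms. That count was 327 without paired replicate 1, 362 without isolated replicate 4 and 1026 with a quality weight per library, added after the data were seen. Both comparisons that define the set use the same isolated libraries, so its members are not independent evidence of a shared change. The set was also chosen on the paired libraries that the comparison of joined with paired worms uses again, so a high share of calls there is partly built in.

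The correlation of the octet and paired fold changes against isolated worms, taken across 40265 transcripts, was 0.73, and unchanged groups simulated against the same isolated libraries gave 0.50. That 0.50 follows from groups of equal size and spread that share controls, so the simulation fixed it in advance and it is no measured baseline. The covariance of the octet and paired fold changes was 0.20, against 0.04 in the simulations, a difference of 0.16. Independent lists of the same lengths would share 70.6 higher and 15.3 lower transcripts, against 544 and 164 observed. The lists of unchanged groups shared 0 transcripts in 20 simulations, but such groups yield few calls by construction, so that value does not measure the part of the overlap due to the shared libraries. With the isolated libraries split 2 and 2 in 6 ways, the correlation averaged 0.46, with a range of 0.32 to 0.59, and the lists shared 155 to 224 higher and 44 to 99 lower transcripts. Independent lists of those lengths would share at most 15.4 higher and 7.29 lower transcripts, and the covariance averaged 0.149. A split leaves 2 isolated libraries per comparison, so the correlation and the lists also shrink through added noise, and not only because no library is shared. For octet and joined fold changes the correlation was -0.08 and, with split controls, -0.24, and the covariance lay 0.06 below that of the simulations. For paired and joined fold changes the correlation was 0.27 and, with split controls, -0.08, with a covariance of 0.0362 against 0.0427 in the simulations. Transcripts are not independent replicates, and no p-value was computed for these correlations.

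Of the 8640 transcripts that differed between octet and isolated worms, the mean of paired worms lay between those of the other 2 groups in 8125 (94.0%), at a median of 0.47 of the way from isolated to octet. For joined worms the mean lay between them in 3096 (35.8%) and beyond the isolated mean in 5536 (64.1%), at a median of -0.10 of the way. These transcripts were chosen on the octet and isolated libraries, so the mean of another group tends to fall between them by selection alone, and no value for unchanged groups was computed. In 547 transcripts octet worms differed from isolated worms and also, in the same direction, from paired worms. Of these 400 were highest in octet worms, among them RNA815_16439, RNA815_30887.2 and RNA815_9549.3, and 147 were lowest there, among them RNA815_6111 and RNA815_256. The 547 rest on the 580 calls between octet and paired worms, a count that ran from 34 to 3988 with 1 library left out. Calls of RNA815_16439, RNA815_6111 and RNA815_256 in that comparison were lost in some alternatives. The joined mean lay below the isolated mean in 314 of the 400 and above it in 132 of the 147.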

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

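Written before their results were seen were the tests of library depth, of the share of RNA815_80.1 and of joined against isolated libraries on an axis; the tests of isolated replicate 3, of the replicate numbers, of paired replicate 4 and octet replicate 3, and the counts over other splits were chosen after.

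A library stood far from the others of its group in 4 of 72 sets of 4 values examined, where chance gives about 1 in 20. The total of octet replicate 1 was 10112451 reads, and the other octet libraries held 7717578 to 7871891. Joined replicate 4 had 64914 transcripts with at least 1 read, against 65590 to 65629 in the other joined libraries. Isolated replicate 3 had a mean Spearman correlation of 0.933 with its own group, against 0.941 to 0.942 for the others. The same library scored -87.2 on the second principal component, against -8.74 to -2.40.

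Octet worms differed in more transcripts from joined worms (14037) than from isolated worms (8640), although joined worms had 24 h of company. Isolated replicate 3 alone did not account for this, because without it the octet against isolated count was 9051, below the 11287 to 13388 found for octet against joined worms with 1 joined library left out. Unequal depth did not account for it either, since with every library thinned to 7302329 reads the ratio of the 2 counts was 1.62. On an axis of 500 transcripts drawn from octet and paired libraries only, joined libraries lay at -0.61 ± 0.14 and isolated libraries at -0.32 ± 0.25 (SD, n = 4 each), an exact two-sided permutation p of 0.0857, where 0.0286 is the smallest possible. Isolated replicate 3 lay at 0.0392 and the other isolated libraries at -0.499 to -0.366, so the distance between the means rests partly on that library. Of the isolated libraries, 2 lay below the highest joined library, at -0.428. Pairs of isolated pools that include replicate 3 differed by a chi-square per degree of freedom of 10.3 to 12.2. The other 3 isolated pools differed by 2.98 to 3.53 and the joined pools by 4.03 to 10.3, so a wider spread among isolated pools rested on replicate 3. With a permutation p of 0.0857 on the axis, such a spread with no shift of joined libraries is not excluded. Chance differences between means of 4 pools stay open beside the biological explanation, in which joined worms move away from the octet state during the first day with a partner.

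Libraries of the same group were spread along a shared axis that held 23.5% of the variance within groups. Its correlation with log2 depth, both centred by group, was -0.229 (permutation p = 0.469, Spearman's rho -0.165 with permutation p = 0.586, r = -0.243 without the 2 libraries of most extreme depth). With the share of RNA815_80.1 it was 0.133 (permutation p = 0.655, rho 0.194 with permutation p = 0.51, r = 0.318 without the 2 most extreme), and both 95% intervals, -0.693 to 0.369 and -0.451 to 0.638, are too wide to exclude either source. Replicate number held 39.2% of the axis, against a median of 21.9% in shufflings within groups (permutation p = 0.198), so a batch shared by equal numbers also stays open, and the labels name none. The column headers number the libraries consecutively in sets of equal replicate number, with each group in every set, but do not say what the sets share. Of the 3 measures compared with the axis, the number of detected transcripts followed it (r = -0.758, permutation p = 0.00175, adjusted 0.00525; rho = -0.712 with permutation p = 0.00978; r = -0.676 without the 2 most extreme), and no biological explanation was tested. That number comes from the same counts as the axis, so part of the correlation may be built in, and no prediction was written for it. In each group the library highest on the shared axis was also highest on the axis of 500 transcripts from octet and paired libraries. These were octet replicate 4, paired replicate 4, joined replicate 4 and isolated replicate 3, at 1.39, 0.328, -0.428 and 0.0392 on the latter. Pools thus varied within groups partly along the direction that separates octet from paired worms. Both axes come from the same counts, and their link was not tested.

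The octet against paired count of 580 depended on single libraries. Paired replicate 4 and octet replicate 3 held it down, as it rose to 3988 without the first and to 2459 without the second. Without any other single octet or paired library it fell, to between 34 and 274. On an axis drawn from the other 6 octet and paired libraries, paired replicate 4 scored -0.169, nearer to the octet mean of 0.214 than to the paired mean of -1.16, and octet replicate 3 scored -0.555, close to the midpoint of -0.472. Both lay outside the octet range of 0.0908 to 0.42 and the paired range of -1.46 to -0.949, but libraries left out of such an axis tend toward its middle by construction. On an axis from the other octet and the isolated libraries octet replicate 3 scored 3.836 and paired replicate 4 scored 3.86, both between the paired replicates 1 to 3 at 3.15 to 3.46 and the other octet libraries at 4.22 to 4.33, and both inside the 95% prediction interval of those paired replicates (2.53 to 4.15). A swap of these 2 libraries therefore cannot be told apart from 2 pools that lie between their groups, and a wrong label of 1 library or real variation among pools remain open; no library was relabelled.

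The counts were also taken over other splits of the same libraries, in 35 splits for each pair of groups. The real split gave the largest count for octet against isolated worms (1 of 35 splits as large, 8640 against a highest other of 208) and paired against isolated worms (1 of 35, 728 against 0). It also did so for joined against paired worms (1 of 35, 1843 against 0) and octet against joined worms (1 of 35, 14037 against 0). No share below 1 of 35 is possible, and no correction was made for the several counts examined. These ranks alone therefore do not exclude chance. For octet against paired worms 2 of 35 splits were as large, and the split that exchanges octet replicate 3 with paired replicate 4 called 7254, more than 580, while the other 33 splits called 0. By the count of splits chance is not excluded there either, and the libraries hold a structure that the groups do not describe. For joined against isolated worms the count was 0 in all 35 splits. Of 60 random regroupings of all 16 libraries, the real one included, only the real one reached 9532 transcripts over the 4 groups (highest other 5083). That is the smallest share that 60 regroupings can give, so it does not exclude chance by itself. None of the 59 other regroupings gave any set of transcripts of constant company, so they do not test the counts taken within that set (546 between joined and paired worms, with 1 of 60 as large and a highest other of 0, and 0 between joined and isolated worms in all 60).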

How the results depend on the processing

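Limma-trend, library weights, the removal of paired replicate 4 with isolated replicate 3, the removal of RNA815_80.1 and the summing of transcripts that share a number were chosen after the data were seen. The alternatives with edgeR and DESeq2 were not run. Over the alternatives other than leaving out 1 library, and except where given here, each count of calls lay within 1.5 times its main value. At a threshold of 0.01 the counts were 4993 over the 4 groups, 3989 for octet against isolated, 319 for paired against isolated, 28 for octet against paired, 632 for joined against paired, 8040 for octet against joined worms and 244 for the constant-company set between joined and paired worms, as a stricter threshold must lower them. In fits to the 8 libraries compared, with fewer samples, the counts were 415 for paired against isolated, 8 for octet against paired and 3 for joined against isolated worms. With a quality weight per library they were 1656 for paired against isolated, 5421 for octet against paired, 3517 for joined against paired worms and 1026 for the constant-company set between joined and paired worms. Without paired replicate 4 and isolated replicate 3, octet against paired worms gave 5205. The cause was not tested for these last 2 settings. With 1 library left out in turn, the range was 6428 to 11609 over the 4 groups, 5617 to 9958 for octet against isolated, 434 to 948 for paired against isolated, 0 to 0 for joined against isolated, 34 to 3988 for octet against paired, 931 to 2317 for joined against paired, 10681 to 15133 for octet against joined worms, and 0 to 0 and 327 to 618 for the constant-company set against isolated and paired worms. Of 540 alternative values of named transcripts, 518 kept their direction and their call, 22 kept their direction and lost their call, all in octet against paired worms, and 0 reversed. Upper-quartile factors moved the median of all transcripts to -0.104 on the log2 scale in octet against joined worms and to -0.0978 in octet against isolated worms, so smaller changes in both are relative to that shift. The replicate numbers were not taken to pair the libraries, since of 24 pairs with the same number 10 had deviations correlated over 0.1, with a range of -0.131 to 0.388. The mean correlation was 0.0824 for the same number and -0.0272 for different numbers, and 8 of 16 libraries were closest to their own number, so a partial link is not excluded. With the replicate block the counts were 1234 for paired against isolated, 2388 for octet against paired (1216 higher and 1172 lower), 2963 for joined against paired worms and 887 for the constant-company set between joined and paired worms, and the cause was not tested. The block also gave 11970 over the 4 groups, 10850 for octet against isolated and 15504 for octet against joined worms, so every count other than 0 was higher with it. For joined against isolated worms the block left 0 calls, with a smallest limma-voom adjusted p of 0.0816, against 0.739 without the block. Fewer scarce transcripts were called, and the part of depth in this was not separated from a real difference by abundance: 9.75% of the 13422 least abundant transcripts were called between octet and isolated worms, against 34.9% of the 13422 most abundant.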

Other observations

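The tests and transcripts in this part were chosen after the data were seen. When the 708 transcripts that mark constant company were adjusted over the list alone, 12 differed between joined and isolated worms (limma-voom), 10 of them toward the level of constant company and 2 away from it. The list was chosen with the same isolated libraries, so this is not independent evidence, and none of the 12 passed over all 40265 transcripts in the fit to 16 libraries, while 3 of them passed in the fit to the 8 joined and isolated libraries. RNA815_34533.2 was at 139 ± 24.7 CPM in isolated, 64.3 ± 12.2 in joined, 40.3 ± 12.3 in paired and 20.1 ± 6.83 CPM in octet worms (SD, n = 4 each), with a limma adjusted p of 0.0136 for joined against isolated worms within the list. RNA815_1838.3 was at 15.9 ± 1.97 CPM in isolated, 6.80 ± 2.55 in joined, 4.25 ± 1.77 in paired and 3.17 ± 1.37 CPM in octet worms, and RNA815_17316 was at 8.57 ± 1.39, 14.3 ± 1.22, 17.0 ± 2.98 and 17.1 ± 1.48 CPM in the same order. The 2 transcripts that went the other way were RNA815_6153 and RNA815_11111.1. RNA815_6153 was at 337 ± 67.6 CPM in isolated, 209 ± 21.5 in joined, 580 ± 50.6 in paired and 863 ± 98.0 CPM in octet worms, so that its joined level lay below all other groups. RNA815_11111.1 was at 101 ± 6.10 CPM in isolated and 70.6 ± 0.79 CPM in joined worms, against 155 ± 24.4 in paired and 210 ± 28.3 CPM in octet worms.

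Near absence in 1 group was rare. With at most 3 reads over the 4 libraries of 1 group and at least 10 reads in every library of the other, 1 transcript was near absent in isolated worms and 1 in octet worms, and 0 in either group of the other 5 comparisons. RNA815_6083.2 had 3 reads in the 4 isolated libraries together, 10 in joined, 15 in paired and 59 in octet libraries. RNA815_45291.2 had 77 reads in the isolated libraries together, 42 in joined, 9 in paired and 1 in octet libraries. Both identifiers share their number with other transcripts, and division of reads between those transcripts was not tested. Among 1540 numbers with at least 2 tested transcripts and a call between octet and isolated worms, 17 held transcripts called in opposite directions. For octet against joined worms the same held for 36 of 2151 numbers.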
